A study of Mus musculus with 29 samples.

How the data were processed

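Sequencing libraries of mouse RNA were made, per the labels, from Trizol extracts of embryos that carry a Dll1-YFP lineage mark on a C57BL/6 background, with the TruSeq RNA v2 kit and 11 rounds of PCR. This kit does not mark the strand of a transcript. The deposited files hold integer counts of aligned reads per gene, made by the authors; per the submitters' processing notes TopHat2 2.0.9, Cufflinks (no version given), HTSeq 0.6 and DESeq2 1.10 were used with the mm10 genome. The annotation, the strand setting and the order of the steps are not given in the sources used here. Each of the 29 files holds 23337 genes and 5 HTSeq summary lines, which were taken out of the gene counts. Reads in no feature made 6.54 to 12.8% of the total, ambiguous reads 0.584 to 1.85%, and reads aligned at more than 1 place 15.9 to 40.6% (38.8 to 39.6% in WT, 40.1 to 40.6% in MUT and at most 25.4% elsewhere). The last of these shares comes from the HTSeq line for alignments that are not unique. It may thus count alignments and not reads, although it is called a share of reads below. Raw reads were not used here.

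Of the 23337 gene symbols 20953 match a gene of GENCODE M21, which was used for coordinates, transcript length and GC content; the build that the authors used is not given. PEAT was matched by its synonyms to AI646519. The library totals over genes ran from 11541131 to 44363411, and a group with 0 counts is given against a floor of 3 counts over that group.

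Libraries were put in 8 groups from their titles and descriptions, and 6 comparisons were made: DIR against CTRL, SOMB against SOMA, SOMC against SOMB, SOMD against SOMC, SOMD against SOMA, and MUT against WT. The SOM libraries were fitted together, and the DIR with CTRL and MUT with WT libraries each in a fit of their own. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested by edgeR 4.0.16 with quasi-likelihood F tests and a prior count of 0.125, under R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Gene lists, 36 with 632 genes of which 631 are in the files, were written before the data were examined, as were the groups, comparisons, naming rule and most of the alternatives. Each list with at least 3 tested members was tested by camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. As alternatives the correlation was estimated from the data, or fry was used, which tests whether a list moves on balance without comparing it with other genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

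Genes were named by a rule. For each comparison except SOMD against SOMA it takes the 5 higher and 5 lower genes with the largest log2 fold change, among those past the threshold with a mean of at least 5 CPM over the compared libraries and no overlap between groups, leaving out Xist, Tsix and 4 Y-linked genes. It adds anchor genes chosen for each comparison, up to 3 members with the lowest p in the direction of each list past the threshold (8 lists at most), and, for MUT against WT, PEAT and genes within 200 kb of Pax1. The report gives the values of only part of these genes; 2 that it would otherwise give are left out. Any gene named outside this rule is said to be chosen after its values were seen. Genes changed by at least 2-fold in DIR against CTRL were tested as 2 further sets along the somite series.

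Alternatives to each result were RLE size factors, library totals without scaling, no filter, replicate number as a block, DESeq2 1.42.0, all 29 libraries in 1 fit, and each library left out in turn. Further settings were chosen after seeing the data: the share of reads aligned at more than 1 place as a term or with only the libraries of low share (DIR and CTRL), the share of reads in no feature as a term and pairs of nearly identical libraries summed (SOM), Xist as a term, only libraries with low Xist, and removal of a trend over transcript length and GC content (MUT and WT). Where leaving out libraries left 1 in a group, that library was taken to vary like the others. Replicate numbers were taken to pair the samples where each same-number pair of a comparison had a correlation over 0.1 of its deviations from the group means. This held in SOMB against SOMA (0.274 to 0.309 over 3 pairs) and SOMD against SOMC (0.241 to 0.323 over 4 pairs) and in no other comparison; the pairing comes from the data, and the labels do not state it. SOM libraries with other numbers deviate together as well, in sets that run along the whole series. SOMA3, SOMB3, SOMC2 and SOMD2 form such a set (0.231 to 0.323), as do SOMA4, SOMB4, SOMC3 and SOMD3 (0.188 to 0.314). SOMA1, SOMB1, SOMC1, SOMC4, SOMD1 and SOMD4 form another (0.196 to 0.309). SOMB2 belongs to none, with 0.112 at most (SOMD3). By these values SOMC against SOMB and SOMD against SOMA also hold matched samples, under other numbers, though the labels do not state it. A block by number does not follow these sets, and joins libraries such as SOMB3 and SOMC3 (−0.107) that do not deviate together. The main SOM fit uses no pairing, so its p-values do not allow for the sets, and no fit was made that follows them. Every split of the libraries of a comparison into groups of the same sizes was fitted in the same way. Pairs of libraries were compared by the median squared difference of their counts over that expected from counting alone. The pipeline was tested on simulated data in which 200 genes had been changed. Of 100 genes changed by 1 log2 unit, edgeR recovered 67 in DIR against CTRL and 95 to 97 in the other comparisons. It recovered 99 or 100 of 100 changed by 2 units. It also called 8 unchanged genes in DIR against CTRL, 8 to 14 in the SOM comparisons and 24 in MUT against WT. Of 35 lists not shifted in the simulation 0 passed camera in each comparison. Genes were simulated independently of each other, so this cannot show how camera behaves where genes vary together. In the real data other splits of the libraries passed up to 24 lists (SOMD against SOMA). Hypotheses about the causes of the differences were left out of the report, except in the section on flagged results.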

Results

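RNA was sequenced from 29 libraries of mouse embryos at E9.0, which fall into 8 groups. CTRL and DIR (n = 4 each) are Dll1-lineage cells of explanted presomitic mesoderm, the unsegmented tissue that forms somites, kept in culture without (CTRL) or with (DIR) the molecules LDN and SAG. The labels call these molecules sclerotome-inducing; the sclerotome is the part of a somite that forms vertebrae and ribs. LDN is known as an inhibitor of BMP receptors, and SAG as an activator of Smoothened in the Hedgehog pathway. SOMA (n = 3), SOMB, SOMC and SOMD (n = 4 each) are uncultured Dll1-lineage cells, sorted by their YFP, from successive levels of the trunk. SOMA holds presomitic mesoderm and the newest somite, SOMB somites 2 to 5, SOMC somites 6 to 9, and SOMD somites from 10 on. Per the labels the last SOMD somite rises by 1 with the replicate number, from 13 in SOMD1 to 16 in SOMD4, so that range is uncertain. SOMC1 and SOMC4 were nearly identical, as were SOMD1 and SOMD4; the labels do not say whether these are repeat libraries of 1 sample, in which case n is 3 for both groups. MUT and WT (n = 3 each) are trunk tissue from which RNA was taken directly. The labels do not say what was mutated; the title of the series names the long non-coding RNA PEAT.

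Gene counts per library ran from 11541131 in SOMD2 to 44363411 in MUT1. They were 22441578 to 37275895 in CTRL, 22897486 to 42002422 in DIR, 14090592 to 28047218 in SOMA, 14319991 to 25497288 in SOMB, 15834045 to 26950283 in SOMC, 11541131 to 27838317 in SOMD, 36004950 to 44363411 in MUT and 31454988 to 34411231 in WT. Levels are given as counts scaled to a common library size by TMM (CPM), as mean ± SD over libraries, and differences as log2 fold changes ± SE. Each CTRL, DIR and SOM library had both the X-inactivation RNA Xist (284.1 to 1828.8 CPM of the library total) and the Y-linked Ddx3y (25.5 to 66.4 CPM). Each of them thus holds RNA of both sexes, from more than 1 embryo. The labels do not say whether the replicates of a group are separate embryos or cultures, so p-values measure the spread between samples, which may be technical.

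Cells cultured with LDN and SAG had higher levels of a transcription factor of the forming sclerotome and of several signalling genes. Pax1, a paired-box factor of the early sclerotome, rose by 3.93 ± 0.45, from 1.34 ± 0.478 CPM in CTRL to 20.4 ± 11.7 CPM in DIR (SD, n = 4 each). Bmp3, a BMP family member that opposes BMP signalling, rose by 3.41 ± 0.27, Fgf4, a growth factor of the tail bud, by 2.87 ± 0.25, and Heyl, a repressor in the Notch pathway, by 2.82 ± 0.28. These are among the 5 largest increases in genes with a mean of at least 5 CPM whose DIR libraries all lay above all CTRL libraries. Their edgeR adjusted p-values ran from 6.48e-04 for Bmp3 to 0.00537 for Pax1. Among genes as abundant, the largest decrease was in Grem1, a secreted BMP antagonist, which fell by 5.07 ± 0.28 (0.575 ± 0.179 against 19.5 ± 3.99 CPM). Next came Smad9, a transducer of BMP signals (−3.63 ± 0.30), Id2, an inhibitor of bHLH factors (−3.15 ± 0.24), Hand1, a factor of lateral plate and heart (−2.34 ± 0.28), and Msx2, a homeobox target of BMP (−2.27 ± 0.21).

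Targets of BMP signalling fell as a list. Of 12 tested, 5 fell and none rose over all genes tested, and 11 fell when adjusted over the list alone (camera adjusted p = 2.86e-35). Id3, with 10.6 ± 9.50 CPM in DIR and 124.4 ± 57.9 in CTRL, did not pass (−3.57 ± 0.70, edgeR adjusted p = 0.0625), nor did Id1 (−1.80 ± 0.58, edgeR adjusted p = 0.218) or Msx1 (−3.20 ± 1.45, edgeR adjusted p = 0.335). All 3 passed with the share of reads aligned at more than 1 place as a term, a setting chosen after seeing the data (edgeR adjusted p = 1.77e-05, 9.23e-04 and 7.45e-05). Of 10 factors of lateral plate and heart field, 6 fell, and 8 when adjusted over the list alone (camera adjusted p = 3.96e-23); among them were Gata5 (−3.19 ± 0.29) and Gata6 (−1.24 ± 0.19). Of 5 factors of the intermediate mesoderm, the source of the kidney, Wt1 fell (−2.24 ± 0.39), and all 5 did when adjusted over the list alone (camera adjusted p = 3.62e-07). These 3 lists are the ones of 18 past the threshold that also held with an estimated correlation (camera adjusted p = 0.0251, 0.0148 and 0.0491).

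The sclerotome list was higher by the set test, with 2 of 7 tested members higher, Pax1 among them, and 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 5.35e-04). That call was lost (adjusted p = 0.274 with an estimated correlation), and the median of the list was 0.09 against a mean of 1.32. Pax9, a close relative of Pax1, had 5.28 ± 3.66 CPM in DIR and 1.29 ± 1.19 in CTRL (2.08 ± 0.74, edgeR adjusted p = 0.257). Sox9, a chondrogenic factor, differed by −0.02 ± 0.17 (edgeR adjusted p = 0.963), and Nkx3-2, a later sclerotome factor, was too low to test, at 0.300 ± 0.152 and 0.194 ± 0.144 CPM. None of the 7 direct targets of Hedgehog signalling passed edgeR, over all genes or adjusted over the list alone, and neither did the list (camera adjusted p = 0.161). They include the pathway's effector Gli1 (−0.06 ± 0.20, edgeR adjusted p = 0.912), its receptor Ptch1 (0.49 ± 0.15, edgeR adjusted p = 0.196) and Hhip (1.11 ± 0.38, edgeR adjusted p = 0.237). With the share of reads aligned at more than 1 place as a term Ptch1 passed (edgeR adjusted p = 0.0480), the only 1 of the 7 to do so, and so did the list (camera adjusted p = 0.0403). In the fit of all 29 libraries Ptch1, Hhip and Pax9 passed (edgeR adjusted p = 0.0478, 0.0091 and 0.0398). Of 4 genes that Hedgehog signalling lowers, the co-receptor gene Boc fell (−0.93 ± 0.17), and 3 did when adjusted over the list alone (camera adjusted p = 5.35e-04). That list's call was lost (adjusted p = 0.127 with an estimated correlation).

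Hox genes of paralogue groups 8 to 13, which pattern the posterior trunk, were lower as a list (camera adjusted p = 3.62e-08). Of 16 tested, Hoxa13 fell (−1.996 ± 0.36), and 9 did when adjusted over the list alone (adjusted p = 0.0937 with an estimated correlation). None of 15 Hox genes of groups 1 to 5 passed over all genes and 9 fell when adjusted over the list alone (camera adjusted p = 5.81e-07, and adjusted p = 0.274 with an estimated correlation). Of 17 immediate early and heat shock genes, Fos (−1.50 ± 0.25) and Fosb (−2.17 ± 0.40) fell, and 5 did when adjusted over the list alone (camera adjusted p = 2.33e-04). That call was also lost (adjusted p = 0.274 with an estimated correlation). None of 7 dermomyotome genes, markers of the dorsal somite, passed over all genes, and 5 fell when adjusted over the list alone (camera adjusted p = 9.20e-04, and adjusted p = 0.0937 with an estimated correlation). Pax3, one of them, differed by −0.89 ± 0.26 (edgeR adjusted p = 0.186, and 0.0307 in the fit of all 29 libraries), while Myf5, the first muscle regulatory factor, fell by 2.996 ± 0.39, from 2.02 ± 0.730 to 0.249 ± 0.0922 CPM (edgeR adjusted p = 0.00907). Scx, a tendon factor, did not pass (0.73 ± 0.64, edgeR adjusted p = 0.61, and 0.0292 with the share of reads aligned at more than 1 place as a term).

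**Figure D1:**
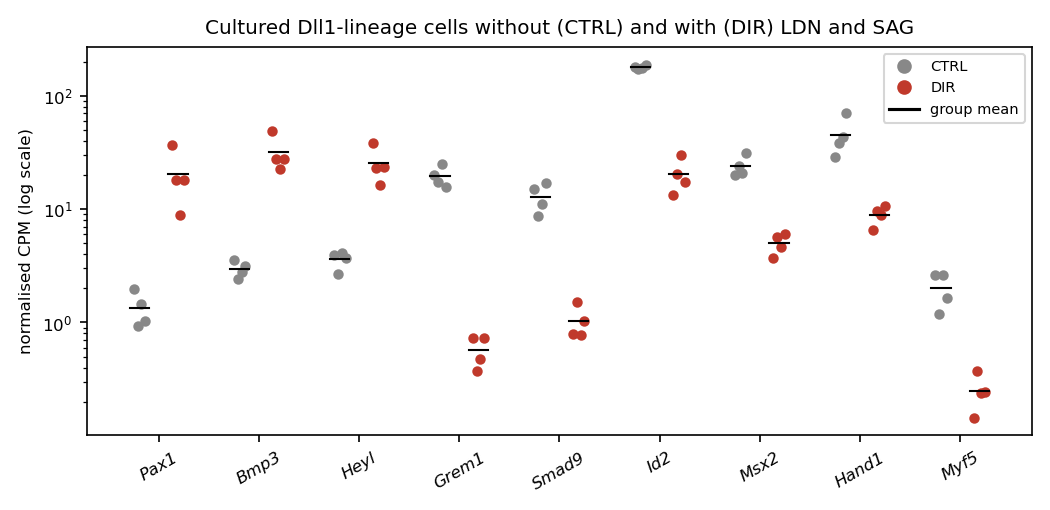
Level of 9 genes (TMM-normalised CPM, log axis) in the 4 CTRL and 4 DIR libraries; each point is a library and each bar the group mean. Every DIR library lies above every CTRL library for Pax1, Bmp3 and Heyl, and below for Grem1, Smad9, Id2, Msx2, Hand1 and Myf5.

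In all, 43 genes rose and 63 fell of 14190 tested by edgeR, 38 and 57 of them by at least 2-fold. The libraries split by their share of reads aligned at more than 1 place (22.3 to 25.4% in CTRL1, DIR1 and DIR2, and 15.9 to 19.5% in the other 5). All 43 and 63 genes had the same sign on both sides of that split, with a median of 1.54 and −1.71 in the 3 libraries with the higher share and 1.61 and −1.70 in the others; for Pax1 the differences were 3.69 and 3.49. Here and in the other comparisons the genes were called from these same libraries, so a shared sign is no independent test. The counts depend on the test and on single libraries. DESeq2 called 207 genes higher and 290 lower, and edgeR without 1 library called 16 (without CTRL4) to 49 (without DIR3) higher and 25 (without CTRL4) to 63 (without CTRL1) lower. Of the 18 named genes past the threshold, 11 passed without any 1 library, and the other 7 did not. Among these were Gata6, Hoxa13, Wt1, Fos, Fosb and Boc, each lost without several libraries, with an edgeR adjusted p of up to 0.169 for Boc.

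The somite series compares successive trunk levels, from unsegmented tissue to older somites. Between SOMA and SOMB, 14 of 16 genes of presomitic mesoderm and tail bud fell, while Pax1, Myf5 and the matrix genes Lum and Dcn were among those that rose. Msgn1, a bHLH factor of presomitic mesoderm, fell by 6.22 ± 0.44, from 29.6 ± 16.0 CPM in SOMA (SD, n = 3) to 0.369 ± 0.228 in SOMB (n = 4). Tbx6, a T-box factor that sets paraxial fate, fell by 5.07 ± 0.47 (66.1 ± 15.2 to 1.86 ± 2.18 CPM). So did T, or brachyury (−4.19 ± 0.29), the segmentation factors Ripply2 (−5.28 ± 0.46) and Mesp2 (−5.14 ± 0.40), and Sv2b, a vesicle protein gene (−5.72 ± 0.50). Pax1 rose by 4.51 ± 0.54 (2.24 ± 2.77 to 60.5 ± 32.0 CPM), the matrix proteoglycan genes Lum by 3.45 ± 0.22 and Dcn by 2.65 ± 0.32, Colec10, a collectin gene, by 3.09 ± 0.27, the zinc finger gene Zic1 by 3.34 ± 0.85 and Myf5 by 3.11 ± 0.42. The edgeR adjusted p-values for these genes ran from 1.22e-07 for Lum to 0.0242 for Zic1.

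Of 16 tested genes of presomitic mesoderm and tail bud, 14 fell, also when adjusted over the list alone (camera adjusted p = 9.70e-49). Of 8 genes of somite boundaries and polarity, 6 fell, and 7 when adjusted over the list alone (camera adjusted p = 6.64e-23). Of 6 Notch targets 3 fell, on both adjustments, Nrarp by 3.64 ± 0.20, Hey1 by 0.99 ± 0.07 and Hey2 by 0.66 ± 0.18 (camera adjusted p = 6.42e-10). The Notch ligand genes Dll3 (−3.82 ± 0.24) and Dll1 (−3.42 ± 0.20) and the modulator Lfng (−2.92 ± 0.19) fell with them. Of 15 Hox genes of groups 1 to 5, 8 fell, Hoxd1 and Hoxb1 among them (−1.63 ± 0.19 and −1.58 ± 0.20), and 11 when adjusted over the list alone (camera adjusted p = 6.42e-10). Of 8 genes of the formed somite 4 rose, on both adjustments (camera adjusted p = 9.45e-06), while Meox1 (0.08 ± 0.17, edgeR adjusted p = 0.907) and Tcf15 (−0.23 ± 0.26, edgeR adjusted p = 0.747) did not pass. Of 4 genes that Hedgehog signalling lowers, 3 rose on both adjustments, the co-receptor genes Cdon (1.21 ± 0.10), Boc (1.01 ± 0.18) and Gas1 (0.89 ± 0.15; camera adjusted p = 1.14e-07). These 6 lists are the ones of 14 past the threshold that also held with an estimated correlation (camera adjusted p = 0.00106, 4.02e-05, 6.50e-04, 0.0379, 0.0399 and 0.0264 in that order).

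Of 8 sclerotome factors 6 rose and 2 fell, on both adjustments (camera adjusted p = 9.52e-06, and adjusted p = 0.101 with an estimated correlation). The 2 that fell, named after their values were seen, were Foxc1 (−0.73) and Foxc2 (−0.52), forkhead factors also expressed in presomitic mesoderm. Among targets of FGF signalling 7 of 11 fell, and 8 when adjusted over the list alone, with Spry2 (−1.03 ± 0.12) and Il17rd (−1.30 ± 0.24) among them (camera adjusted p = 1.26e-08, and adjusted p = 0.121 with an estimated correlation). Of 20 genes of cholesterol synthesis 9 fell, and 16 when adjusted over the list alone (camera adjusted p = 3.71e-10, and adjusted p = 0.235 with an estimated correlation). The enzyme genes Hmgcs1 and Cyp51 each fell by 0.60, with SE 0.10 and 0.11. Of 18 matrix genes 6 rose and 2 fell, and 9 and 2 when adjusted over the list alone (camera adjusted p = 1.07e-09, and adjusted p = 0.121 with an estimated correlation). Gli1 did not pass (0.57 ± 0.26, edgeR adjusted p = 0.229, and 0.0090 without SOMA1), with 1 of 7 Hedgehog targets higher on both adjustments (camera adjusted p = 0.0278, and adjusted p = 0.425 with an estimated correlation). Pax3 did not pass either (0.28 ± 0.26, edgeR adjusted p = 0.675).

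In all, 575 genes rose and 631 fell from SOMA to SOMB of 13790 tested by edgeR. The share of reads in no annotated gene split the series (12.0 to 12.8% in SOMA1, SOMB1, SOMC1, SOMC4, SOMD1 and SOMD4, and 7.57 to 10.7% in the other 9 libraries). Those with the higher share also deviate together between groups (0.196 to 0.309), so the split parts 1 set of libraries from the rest. Its SOMC and SOMD members are the nearly identical pairs. In the libraries with the higher share, 1 per group, 574 of the 575 and all 631 genes had the same sign, and in the others all had; for Pax1 the differences were 3.38 and 6.48. Without SOMA4, 357 genes rose; the fit of all 29 libraries called 343 higher and 432 lower. Zic1 did not pass without SOMA3, SOMA4 or SOMB2 (edgeR adjusted p up to 0.121), nor Hey2 without SOMA1, SOMA4, SOMB2, SOMB3 or SOMB4 (up to 0.13).

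From SOMB to SOMC, Nkx3-2, Col2a1, Col9a1 and Myog rose, and the Notch pathway genes Hey1, Hey2 and Dll3 and the tail bud genes Cdx4 and Evx1 fell. Nkx3-2, a homeobox factor of the chondrogenic sclerotome, rose by 1.40 ± 0.25, from 2.32 ± 0.711 to 6.28 ± 0.921 CPM (SD, n = 4 each; edgeR adjusted p = 0.0171). Cartilage collagen genes Col2a1 and Col9a1 rose by 0.98 ± 0.13 and 1.12 ± 0.22, the matrix gene Lum by 1.15 ± 0.15, and Myog, the muscle differentiation factor, by 4.48 ± 0.90 (0.0813 ± 0.0727 to 2.07 ± 1.81 CPM; edgeR adjusted p = 0.0389). The 5 largest increases among the more abundant genes were in Epha3 (1.88 ± 0.38), a receptor of ephrins, Alcam (1.82 ± 0.27), a cell adhesion molecule, Chrna4 (1.78 ± 0.24), an acetylcholine receptor subunit, Sema3d (1.74 ± 0.24), a guidance cue, and Tdo2 (1.66 ± 0.20), an enzyme of tryptophan breakdown. The 5 largest decreases were in Dll3 (−1.39 ± 0.26), Fgf18 (−1.38 ± 0.24), Ifitm1 (−1.37 ± 0.20), Gdnf (−1.32 ± 0.26) and Ptprz1 (−1.31 ± 0.22). Pax1 did not pass (0.00 ± 0.38, edgeR adjusted p = 0.999), nor did Pax9 (0.33 ± 0.40, edgeR adjusted p = 0.734), Sox9 (0.64 ± 0.26, edgeR adjusted p = 0.349), Myf5 (0.28 ± 0.30, edgeR adjusted p = 0.698), Scx (0.36 ± 0.31, edgeR adjusted p = 0.637) or Gli1 (0.19 ± 0.23, edgeR adjusted p = 0.738).

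Of 6 Notch targets Hey1 and Hey2 fell (−0.69 ± 0.06 and −0.82 ± 0.17), and 3 did when adjusted over the list alone (camera adjusted p = 2.63e-06). None of 12 BMP targets passed edgeR over all genes, and 5 rose when adjusted over the list alone (camera adjusted p = 7.39e-06). These 2 lists, of 20 past the threshold, also held with an estimated correlation (camera adjusted p = 0.0097 and 0.0452). Of 16 genes of presomitic mesoderm and tail bud Cdx4 (−2.87 ± 0.52), Evx1 (−1.75 ± 0.39) and Dll3 fell, and 6 did when adjusted over the list alone (camera adjusted p = 3.31e-07, and adjusted p = 0.243 with an estimated correlation). Of 20 genes of cholesterol synthesis 4 fell, Idi1 by 0.72 ± 0.12, and 13 when adjusted over the list alone (camera adjusted p = 3.57e-16, and adjusted p = 0.226 with an estimated correlation). Of 18 matrix genes Lum alone rose over all genes and 7 when adjusted over the list alone (camera adjusted p = 9.68e-07, and adjusted p = 0.243 with an estimated correlation). Of 11 cartilage genes 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 4.85e-05, and adjusted p = 0.243 with an estimated correlation). Of 21 muscle genes 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 2.41e-04, and adjusted p = 0.345 with an estimated correlation).

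In all, 68 genes rose and 51 fell of 13790 tested by edgeR, each with the same sign in the libraries with a higher and with a lower share of reads in no gene (medians 1.06 and −0.71, and 0.998 and −0.72). For Nkx3-2 the differences were 1.38 and 1.37. SOMC1 and SOMC4 differed from each other by 1.61 times the variance of counting alone (95% interval 1.55 to 1.67), and SOMD1 and SOMD4 by 1.54 times (1.48 to 1.59), against 3.94 to 14.7 times in the other pairs of the series. With each of these pairs summed to 1 library, a setting chosen after seeing the data, 11 genes rose and 4 fell, and 8 of the 22 named genes past the threshold still passed, Hey1, Tdo2, Lum, Col2a1, Chrna4, Sema3d, Ifitm1 and Alcam. Without 1 library 17 (without SOMB4 or SOMC4) to 86 (without SOMA1) genes rose and 9 (without SOMB4) to 69 (without SOMB2) fell. DESeq2 called 158 and 127, and Nkx3-2 did not pass without SOMB4, SOMC1 or SOMC4 (edgeR adjusted p up to 0.0695). Of the 22 named genes past the threshold 9 passed without any 1 library. In the 15 fits that leave out 1 library Evx1 passed in 3, and Myog, Hey2, Epha3 and Gdnf in 8. Dll3, Cdx4 and Col9a1 passed in 10, Fgf18 in 12 and Ptprz1 in 13.

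From SOMC to SOMD, 6 of 21 muscle genes and the transcription factor genes Barx1, Lhx9 and Tfap2c rose, and 5 of 16 Hox genes of groups 8 to 13 fell. Barx1, a homeobox factor known from facial and stomach mesenchyme, rose by 5.27 ± 0.35, from 0.696 ± 0.335 to 25.5 ± 9.46 CPM (SD, n = 4 each; edgeR adjusted p = 1.50e-06). Lhx9, a LIM homeobox factor, rose by 3.97 ± 0.71, Tfap2c, an AP-2 factor, by 3.56 ± 0.63, C130021I20Rik by 3.15 ± 0.58, and Dcx, a microtubule protein of young neurons, by 2.58 ± 0.37. Pitx1, a homeobox factor of the hindlimb, fell by 4.39 ± 0.47 (46.2 ± 28.9 to 2.25 ± 0.521 CPM), and so did 2610528A11Rik (−3.55 ± 0.38), Hoxc9 (−2.94 ± 0.35) and Hoxc8 (−2.22 ± 0.24). Hoxc10 had 1041 counts over the 4 SOMC libraries and 2 over the 4 SOMD libraries, a CPM ratio of 448 (95% counting interval 124 to 3704; edgeR adjusted p = 0.0391). These 5 genes of sclerotome and cartilage did not pass: Pax1 (0.30 ± 0.38, edgeR adjusted p = 0.967), Pax9 (0.36 ± 0.40, edgeR adjusted p = 0.95), Nkx3-2 (0.66 ± 0.23, edgeR adjusted p = 0.203, and 0.0415 with the share of reads in no gene as a term, a setting chosen after seeing the data), Sox9 (0.22 ± 0.26, edgeR adjusted p = 0.957) and Col2a1 (0.22 ± 0.13, edgeR adjusted p = 0.602). Nkx3-2 passed in that 1 of 23 alternatives only, and had an edgeR adjusted p of 0.682 with nearly identical libraries summed.

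Of 21 muscle genes 6 rose, and 12 when adjusted over the list alone (camera adjusted p = 7.07e-15, and adjusted p = 0.0531 with an estimated correlation). Among them were Myog (2.15 ± 0.52, edgeR adjusted p = 0.0494) and the sarcomere genes Myl4 (3.25 ± 0.57), Tnnt2 (2.42 ± 0.40) and Ttn (2.34 ± 0.37), while the determination factor Myf5 did not pass (−0.06 ± 0.30, edgeR adjusted p = 0.996). Of 16 Hox genes of groups 8 to 13, 5 fell, and 5 fell and 1 rose when adjusted over the list alone (camera adjusted p = 5.56e-05, and adjusted p = 0.376 with an estimated correlation). The median of that list was 0.09 while its mean was −0.70 and its test pointed down. Of 15 Hox genes of groups 1 to 5, 4 rose, Hoxa4 by 1.09 ± 0.14 and Hoxc5 by 0.72 ± 0.13, and 5 when adjusted over the list alone (camera adjusted p = 1.07e-06, and adjusted p = 0.104 with an estimated correlation). Of 9 genes of surface ectoderm and other epithelia the keratin gene Krt19 fell (−1.41 ± 0.12), and 3 did when adjusted over the list alone (camera adjusted p = 3.06e-07, and adjusted p = 0.0531 with an estimated correlation). None of the 14 lists past the threshold held with an estimated correlation; the lowest adjusted p was 0.0531.

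In all, 176 genes rose and 149 fell of 13790 tested by edgeR, each with the same sign in the libraries with a higher and with a lower share of reads in no gene (medians 1.38 and −1.08, and 0.95 and −0.76). For Barx1 the differences were 6.11 and 4.25. The side with the higher share holds SOMC1 and SOMC4 against SOMD1 and SOMD4, the nearly identical pairs. It may thus rest on 1 sample per group. With SOMC1 and SOMC4, and SOMD1 and SOMD4, summed to 1 library each, 20 genes rose and 32 fell. Of the 25 named genes past the threshold 11 still passed, Barx1, Krt19, Hoxc8 and Pitx1 among them. Among those lost were Lhx9, Tfap2c and C130021I20Rik (edgeR adjusted p = 0.0787, 0.0669 and 0.0948). Without 1 library 61 (without SOMD4) to 213 (without SOMD3) genes rose and 69 (without SOMD4) to 189 (without SOMB2) fell. Of the 25 named genes 16 passed without any 1 library. The calls of Hoxc10, Myog and Cdx2 were lost without SOMD4 (edgeR adjusted p = 0.278, 0.186 and 0.233) and without several other libraries.

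**Figure D2:**
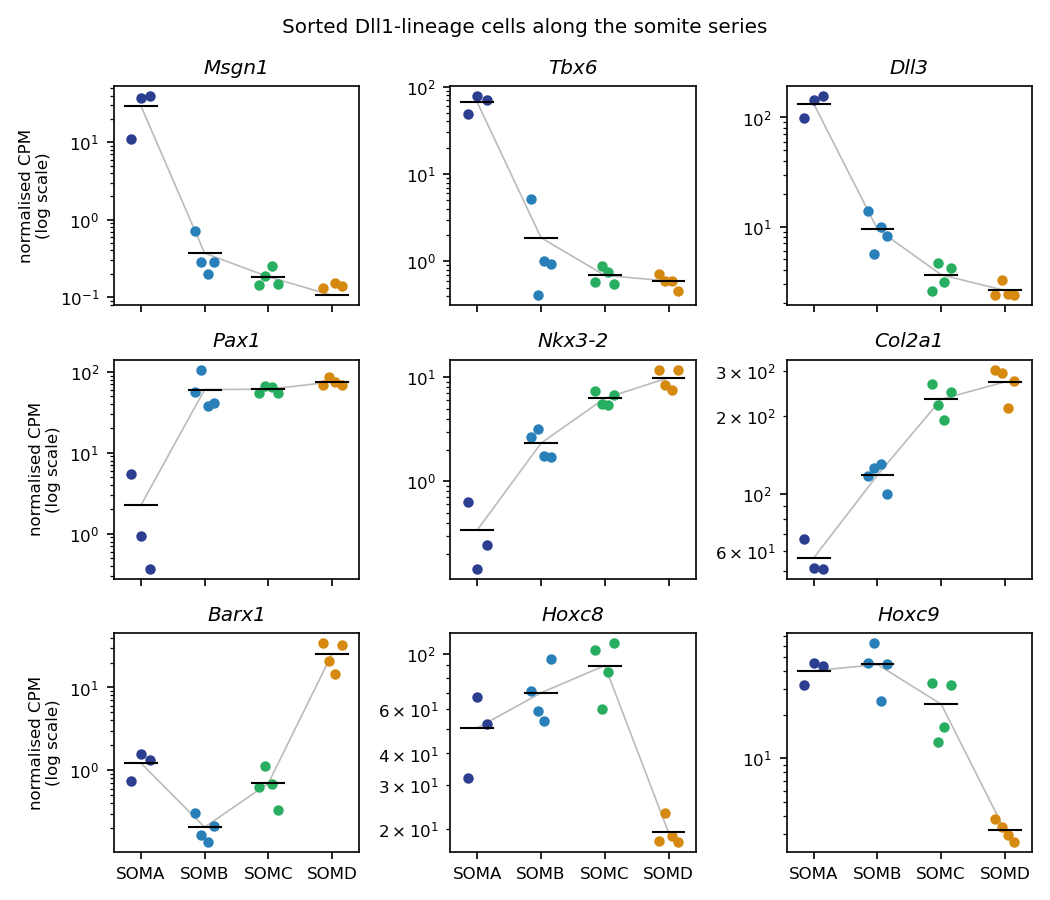
Level of 9 genes (TMM-normalised CPM, log axes) in the SOMA, SOMB, SOMC and SOMD libraries; points are libraries, bars are group means and grey lines join the means. Msgn1, Tbx6 and Dll3 fell from SOMA to SOMB, Pax1 rose over the same step, Nkx3-2 and Col2a1 rose from SOMB to SOMC, and Barx1 rose and Hoxc8 and Hoxc9 fell from SOMC to SOMD; 1 SOMD library with 0 counts of Msgn1 lies off the log axis.

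Over the whole series, from SOMA to SOMD, 5 of 8 sclerotome and 17 of 21 muscle genes rose (2 fell in each), and 14 of 16 genes of presomitic mesoderm and tail bud fell. Pax1 rose by 4.81 ± 0.55 (to 75.1 ± 7.86 CPM, SD, n = 4), Pax9 by 3.08 ± 0.52, Nkx3-2 by 4.64 ± 0.36, Sox9 by 2.82 ± 0.32 and Lum by 4.48 ± 0.22. Myf5 rose by 3.32 ± 0.42, Cdh15, a cadherin of muscle precursors, by 4.13 ± 0.42 and Ttn by 3.78 ± 0.48. Myog had 0 counts over the 3 SOMA libraries and 717 over the SOMD libraries, at least 204-fold higher against a floor of 3 counts over the SOMA group. Mesp2 (−7.81 ± 0.52), Ripply2 (−7.35 ± 0.57), T (−6.51 ± 0.36) and Dll3 (−5.71 ± 0.28) fell. Hoxc10 had 8339 counts in SOMA and 2 in SOMD, a CPM ratio of 4874 (95% counting interval 1349 to 40254), and Hoxc11 542 and 2, a ratio of 317 (87.3 to 2623). Gli1 (0.63 ± 0.26, edgeR adjusted p = 0.102, and 0.0407 with the share of reads in no gene as a term, and 1.08 with adjusted p = 0.00297 without SOMA1), Pax3 (−0.42 ± 0.26, edgeR adjusted p = 0.294) and Scx (0.12 ± 0.33, edgeR adjusted p = 0.841) did not pass. Gli1 passed in 3 of 23 alternatives, and had an edgeR adjusted p of 0.204 with nearly identical libraries summed.

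In all, 1493 genes rose and 1222 fell from SOMA to SOMD of 13790 tested by edgeR. Of 6 Notch targets 4 fell, of 8 genes of somite boundaries 7, and of 16 presomitic and tail bud genes 14, each the same when adjusted over the list alone. These are the 3 of 17 lists past the threshold that also held with an estimated correlation (camera adjusted p = 1.55e-04, 0.00148 and 0.00421). Of 21 muscle genes 17 rose and 2 fell, and 18 and 2 when adjusted over the list alone (camera adjusted p = 1.42e-08, and adjusted p = 0.155 with an estimated correlation). The 2 that fell, named after their values were seen, were Des (−0.44) and Myl1 (−1.32), genes of the muscle filament. Of 8 sclerotome factors 5 rose and 2 fell, on both adjustments (camera adjusted p = 0.00108, and adjusted p = 0.207 with an estimated correlation). Of 16 Hox genes of groups 8 to 13, 10 fell, and 13 when adjusted over the list alone (camera adjusted p = 3.12e-06, and adjusted p = 0.279 with an estimated correlation). In the libraries with a higher share of reads in no gene, 1492 of the 1493 and 1221 of the 1222 genes had the same sign, and in the others all had; for Pax1 the differences were 3.67 and 7.04. Of the 29 named genes past the threshold only Gas1 was lost without 1 library (SOMA3, SOMA4, SOMD1 or SOMD4; edgeR adjusted p up to 0.133).

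Genes that LDN and SAG changed in culture by at least 2-fold were then followed along the series, as 1 set of 38 higher and 1 of 57 lower genes. From SOMB to SOMC the set raised by LDN and SAG was lower, with 3 of 36 tested members lower and none higher by edgeR over all genes, and 6 lower when adjusted over the list alone (camera adjusted p = 1.92e-07, and adjusted p = 0.049994 with an estimated correlation). The set lowered by LDN and SAG was higher over the same step, with 3 of 55 members higher and 1 lower, and 15 and 4 when adjusted over the list alone (camera adjusted p = 5.59e-05, and adjusted p = 0.188 with an estimated correlation). From SOMC to SOMD the lowered set was lower, with 2 members higher and 5 lower, and 5 and 16 when adjusted over the list alone (camera adjusted p = 1.42e-06, and adjusted p = 0.226 with an estimated correlation). The raised set did not pass there, with 5 members higher and none lower, and 6 and 4 when adjusted over the list alone (camera adjusted p = 0.65). From SOMA to SOMB neither set passed (camera adjusted p = 0.545 for both), with 11 members of the raised set higher and 8 lower (14 and 10 when adjusted over the list alone), and 9 and 7 of the lowered set (11 and 11). From SOMA to SOMD neither passed (camera adjusted p = 0.255 and 0.853).

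In the files PEAT is the gene AI646519, which in GENCODE M21 overlaps the first exon of the Pax1 transcript Pax1-202 on the opposite strand. The other annotated Pax1 transcripts start at 147364994 and 147368282, beyond the end of PEAT. In mm10 the annotation puts PEAT on chromosome 2 from 147357454 to 147362793 (minus strand) and Pax1 from 147361925 to 147393295 (plus strand). The library kit does not mark strand, so reads of the shared stretch cannot be assigned to 1 of them, and the values of both genes are uncertain there. In MUT, PEAT had 0 counts in each of 3 libraries, which together held 3682 counts of Pax1. In WT it had 25, 18 and 61 counts (1.02 ± 0.635 CPM, SD, n = 3), 104 in all beside 4488 of Pax1. Against a floor of 3 counts over the MUT group, PEAT was at least 40.7-fold lower (edgeR adjusted p = 0.0329); at the WT ratio to Pax1, 85.3 counts would have been present. The call of AI646519 was lost without any 1 of the 6 libraries (edgeR adjusted p from 0.058 without WT2 to 0.113 without MUT2), and its adjusted p was up to 0.31 over the alternatives, while the MUT counts stayed at 0. Intervals and floors given here cover counting error only.

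Pax1 itself had 32.3 ± 12.6 CPM in MUT and 44.4 ± 17.4 in WT (−0.46 ± 0.41, edgeR adjusted p = 0.7). Over the alternatives it differed by −1.09 to −0.0961 and passed in none (lowest edgeR adjusted p = 0.0671), and the difference between MUT1 and WT was −1.02. Nkx2-2, a factor of the ventral neural tube within 200 kb of Pax1, did not pass (0.17 ± 0.40, edgeR adjusted p = 0.9). Outside that window, Foxa2, a factor of notochord and floor plate, did not pass either (−0.10 ± 0.25, edgeR adjusted p = 0.902). Nor did Xrn2, an exonuclease gene (−0.03 ± 0.05, edgeR adjusted p = 0.831), while Nkx2-4, also outside the window, was too low to test. The sclerotome factors Pax9 (−0.34 ± 0.67, edgeR adjusted p = 0.876), Nkx3-2 (−0.36 ± 0.42, edgeR adjusted p = 0.765) and Sox9 (−0.13 ± 0.14, edgeR adjusted p = 0.738) did not pass. None of 8 sclerotome and 12 cartilage genes passed edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.96 and 0.967).

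Genes for ribosomal proteins and for the respiratory chain were higher in MUT. Of 78 cytosolic ribosomal protein genes 29 rose, and 59 when adjusted over the list alone, with a median log2 fold change of 0.48 (camera adjusted p = 1.52e-70, and adjusted p = 0.177 with an estimated correlation). The study is known to report this list for the mutant, so neither count is independent evidence of its direction. Rpl41 rose by 1.18 ± 0.11 (44.5 ± 7.31 to 101.0 ± 4.34 CPM, SD, n = 3 each) and Rpl13a by 0.76 ± 0.07. Of 55 nuclear genes for subunits of the respiratory chain 9 rose, and 30 rose and 1 fell when adjusted over the list alone (camera adjusted p = 9.40e-24, and adjusted p = 0.177 with an estimated correlation); Ndufb3 rose by 0.85 ± 0.12 and Ndufs7 by 0.72 ± 0.10. Of 76 mitochondrial ribosomal protein genes 6 rose, and 24 when adjusted over the list alone (camera adjusted p = 4.84e-18, and adjusted p = 0.177 with an estimated correlation). Of 28 translation factors Eif3g (0.57 ± 0.07), Eef1d (0.53 ± 0.10) and Eef1b2 (0.36 ± 0.06) rose, and 9 did when adjusted over the list alone (camera adjusted p = 8.88e-09, and adjusted p = 0.893 with an estimated correlation).

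The 5 largest increases among the more abundant genes were in Romo1 (1.41 ± 0.25) and Atp5k (0.95 ± 0.16), small mitochondrial proteins, Rpl41, Polr2f (0.92 ± 0.11), a shared subunit of RNA polymerases, and Ndufa7 (0.91 ± 0.16). The 5 largest decreases were Pgap1 (−0.45 ± 0.08), Lnp (−0.39 ± 0.07), Zfand6 (−0.39 ± 0.07), Avl9 (−0.38 ± 0.07) and Fam179b (−0.37 ± 0.06), none of them 2-fold. Markers of endoderm and yolk sac, tissue that can lie beside the trunk, were lower as a list (median −1.86; camera adjusted p = 0.0215, and adjusted p = 0.997 with an estimated correlation), with none of 9 past edgeR, over all genes or adjusted over the list alone. Cubn, a receptor of the yolk sac, had 2.38 ± 0.833 CPM in MUT and 14.2 ± 17.3 in WT (edgeR adjusted p = 0.373). None of the 8 lists past the threshold held with an estimated correlation; the lowest adjusted p was 0.177.

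In all, 133 genes rose and 22 fell of 14485 tested by edgeR, 2 and 1 of them by at least 2-fold. MUT2 and MUT3 had 1920.7 and 1920.2 CPM of the X-inactivation RNA Xist and under 1 CPM of the Y-linked genes Ddx3y and Eif2s3y, while MUT1 had 2.30 CPM of Xist and the WT libraries 3.14 to 11.6. Between MUT1 and the WT libraries the medians of the 133 and 22 genes were 0.55 and −0.33, but the genes were called with MUT1 included, so this does not separate sex from mutation; no WT library had high Xist, so no value can be had on the other side. With Xist as a term the difference of MUT from WT rests on MUT1 alone, since MUT2 and MUT3 make up the high-Xist class. That fit thus sets 1 MUT library against 3 WT libraries. Its calls cannot show whether sex accounts for those of the main fit. In MUT1 Rpl13a was 0.90 above the WT libraries on the log2 scale. Without 1 library 1 (without MUT3) to 115 (without WT3) genes rose and 0 to 40 (without WT3) fell, and of the named genes past the threshold Rpl13a alone passed each time.

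**Figure D3:**
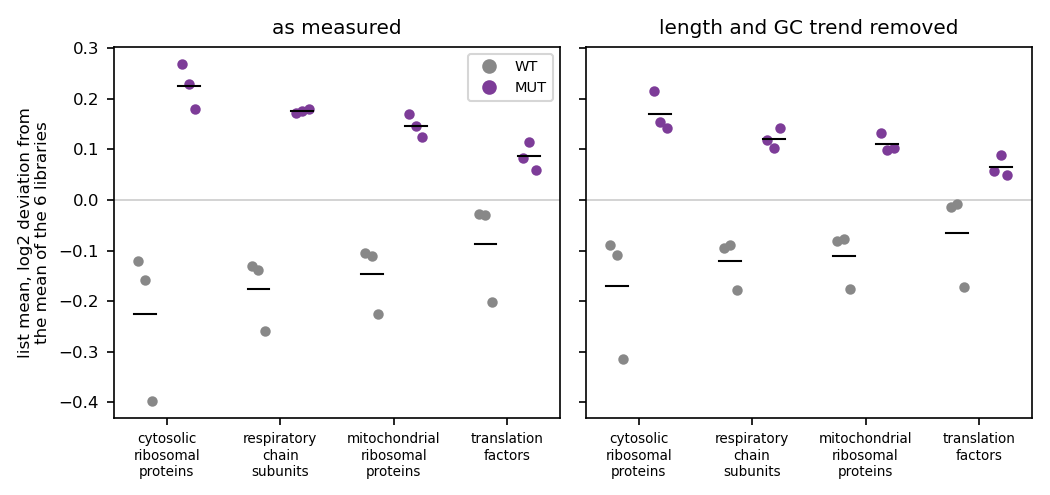
Mean over the genes of 4 lists of the log2 level in each MUT and WT library, as a deviation from the mean of the 6 libraries; points are libraries and bars group means, as measured (left) and after removal of a trend over transcript length and GC content (right). In all 4 lists every MUT library lies above every WT library on both sides, and the ribosomal protein difference is 0.45 on the left and 0.34 on the right.

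PEAT was also compared across the other groups, a choice made after its values were seen. Its counts were 7, 2, 0 and 4 in CTRL and 125, 43, 23 and 27 in DIR (AI646519, 3.90 ± 0.65, edgeR adjusted p = 0.0316), with Pax1 at 3.93 ± 0.45 in the same comparison. From SOMA to SOMB it rose by 4.80 (edgeR adjusted p = 4.49e-04), from 3 counts over the 3 SOMA libraries to 132 over the 4 SOMB libraries. It did not pass from SOMB to SOMC (−0.07) or from SOMC to SOMD (0.53, edgeR adjusted p = 0.77). Per 100 counts of Pax1 there were 7.93 ± 3.31 of PEAT in DIR (SD, n = 4) and 2.62 ± 0.638 over the SOMB, SOMC and SOMD libraries (n = 12). Every DIR library (5.14 at the lowest) lay above every SOMB, SOMC and SOMD library (3.50 at the highest). CTRL had 6.96 ± 5.22 (SD, n = 4) and SOMA 5.34 ± 8.70 (SD, n = 3), on 13 and 3 counts of PEAT in all, so the ratio is not known to differ between DIR and CTRL. The CTRL libraries ran from 0 to 12.1, and the SOMA mean comes from SOMA3 (15.4, with 2 counts of PEAT), against 0.645 in SOMA1, 0 in SOMA4 and 1.72 with the counts pooled. The WT libraries had 2.18 ± 0.482 (SD, n = 3).

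**Figure D4:**
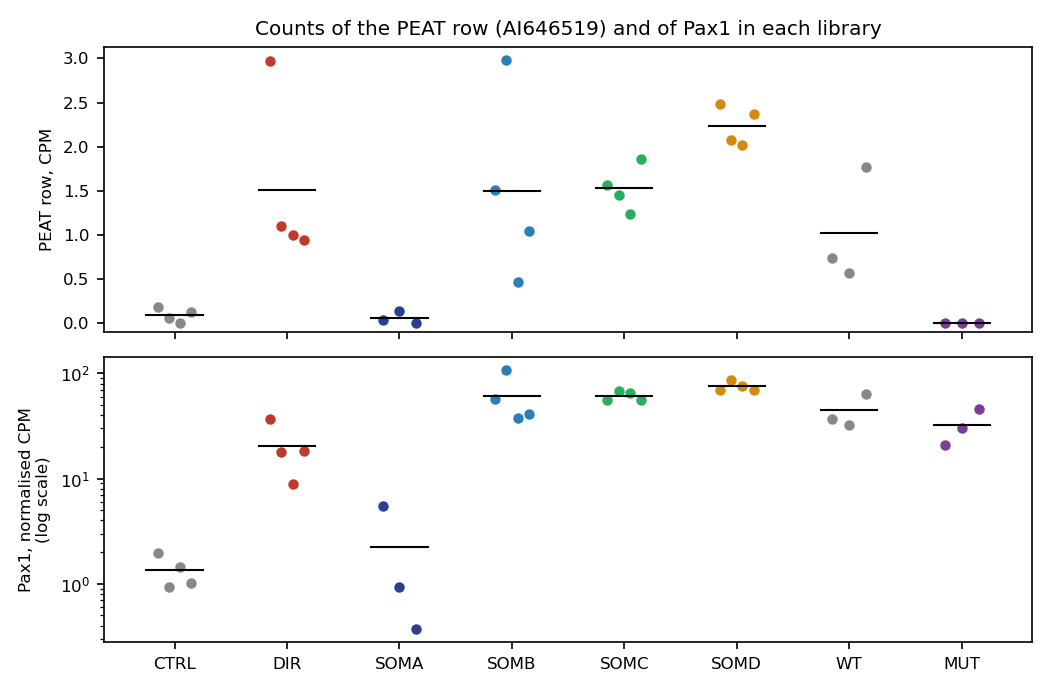
CPM of PEAT (AI646519, top) and TMM-normalised CPM of Pax1 (bottom, log axis) in all 29 libraries by group; points are libraries and bars group means. PEAT is at 0 counts in the 3 MUT libraries, where Pax1 has 32.3 ± 12.6 CPM, and both genes are low in CTRL and SOMA.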

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

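All tests of explanations in this part were chosen only after the result was seen. Groups of 4 libraries were screened for a library that stood apart, and SOMA, MUT and WT (n = 3 each) were not. In a screened group, a library was singled out where its gap to the nearest of the others was most of the group's range. Of 169 groups of values, 13 had such a library, and chance gives about 1 in 20. No explanation was tested for the values in the next paragraph.

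CTRL1 had 22.7% of its reads aligned at more than 1 place, against 15.9 to 17.0% in the other CTRL libraries, and 38.1 CPM of Id3 against 148 to 162. AI646519 was at 3.01 CPM in DIR1 and 0.934 to 1.11 in the other DIR libraries. Xist was at 284.1 CPM in SOMB2 (others 803 to 889) and at 1016.2 in SOMC4 (others 973 to 980). SOMB2 had 4.37 CPM of Ptprz1 (others 9.33 to 10.3), and SOMB3 had 62.2 CPM of Pax3 (others 49.5 to 51.7) and 4.43 of Chrna4 (others 1.68 to 2.14). Gli1 was at 76.0 CPM in SOMC3 (others 105 to 109.6), Dcx at 2.00 in SOMC4 (others 1.57 to 1.60), and Hoxc10 at 0.0700 in SOMD4 (0 counts in the others). Outside the gene counts, the lowest share of reads aligned at more than 1 place in MUT was 40.1%, above the highest in WT (39.6%).

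In SOMB1, Msgn1 was at 0.706 CPM (others 0.201 to 0.286) and Tbx6 at 5.12 (others 0.408 to 1.01). Both are genes of presomitic mesoderm, which the SOMA libraries hold. Over 97 other genes lower in SOMB than in SOMA, SOMB1 was shifted towards SOMA by a median of 6.41% (95% interval 5.73 to 7.62%). Of the 97, 83 lay above the mean of the other SOMB libraries. The median was −5.47% in SOMB2 (−7.36 to −4.19%), −1.41% in SOMB3 (−3.32 to 0.223%) and −1.62% in SOMB4 (−3.29 to −0.611%). Each of these was set against a mean that includes SOMB1. The intervals resample genes within 1 library, so they do not cover the spread between libraries. A candidate explanation is thus some tissue of the SOMA level in SOMB1, though Msgn1 itself was shifted by 1.53% and Tbx6 by 6.63%. A difference in the stage of the embryos used stays open, since no value here separates it from carried-over tissue. SOMA1, which deviates together with SOMB1 (0.309), had the most Pax1 counts of the SOMA libraries (155, against 13 and 6). Whether SOMA1 is shifted towards SOMB was not tested.

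Genes for ribosomal proteins were higher in MUT, by a mean of 0.45 (SE 0.0903) on the log2 scale. A trend over transcript length and GC content in unlisted genes parted the groups completely. Per doubling of length it was −0.036 to −0.026 in the MUT libraries and 0.018 to 0.050 in WT. Per 10% of GC it was 0.034 to 0.088 and −0.095 to −0.037. After this trend was removed the difference was 0.34 (SE 0.0758), which argues against that trend as the whole cause, though it accounts for part of the size. The 14 members with under 20% of their sequence words shared with other genes differed by 0.37 (SE 0.0828), which argues against reads shared between copies as the whole cause. Embryo sex and mutation cannot be told apart in MUT2 and MUT3, because no WT library had high Xist; in MUT1 alone the median of the list against WT was 0.53. What stays open is a biological difference of the mutant, sex, and any handling that the groups do not share.

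PEAT counts went with those of Pax1 over the groups, and the genes overlap on a kit that does not mark strand. If PEAT counts were a constant share of Pax1 reads, their ratio would not differ between groups; it was higher in DIR than in SOMB, SOMC and SOMD (exact permutation p = 5.49e-04, the smallest these splits can give). With nearly identical libraries summed it was 9.99e-04; neither value allows for libraries of successive levels that deviate together. In CTRL the ratio was 6.96 ± 5.22 (SD, n = 4) on 13 counts of PEAT, too few to say whether it differs from DIR, so the difference may not be particular to LDN and SAG. A share that differs between cultured and sorted libraries, or with the Pax1 transcript made in each group, stays open.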

How the results depend on the processing

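The terms for read shares and Xist, the fits of libraries with a low share or low Xist, the summing of nearly identical libraries and the removal of a length and GC trend were chosen only after the result was seen. Of 4640 values of named genes under the alternatives, 4107 kept their side of the threshold, 427 no longer passed, 106 newly passed and 0 changed direction with a pass in either fit (some genes that passed in neither changed sign); of 1903 values of lists the numbers were 1730, 170, 0 and 3. No gene called by edgeR in a comparison had the other sign where an alternative also called it. Where a cause is not given below, the cause was not tested.

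In DIR against CTRL the counts of 43 higher and 63 lower genes became 207 and 290 with DESeq2, 804 and 678 in the fit of all 29 libraries, 320 and 442 with the share of reads aligned at more than 1 place as a term, and 106 and 151 with only the libraries of low share (37 and 60 of them shared). With replicate number as a block, 181 were lower; replicate numbers do not show a pairing, since the same-number pairs of this fit correlated from −0.476 to 0.701. Lists past the threshold fell from 18 to 3 with an estimated correlation and 8 with fry. Leaving out 1 library gave 16 (CTRL4) to 49 (DIR3) higher and 25 (CTRL4) to 63 (CTRL1) lower, and 14 to 22 lists. The higher count was also 20 without CTRL2, 18 without CTRL3, 24 without DIR2 and 20 without DIR4, and the lower count 28, 27, 36 and 31, and 34 without DIR1.

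With replicate number as a block, 530 genes were higher and 613 lower in SOMB against SOMA (575 and 631 without) and 202 and 181 in SOMD against SOMC (176 and 149 without), the 2 comparisons in which the numbers pair the samples. In SOMD against SOMC Spry2 no longer passed (edgeR adjusted p = 0.0566 in place of 0.0412) and Evx1 newly passed (0.02115 in place of 0.0626). The block changed no other call of a named gene or list in these 2. It was fitted over all SOM libraries, so it also joined libraries that do not deviate together, such as SOMB3 and SOMC3 (−0.107). No fit paired the libraries of either comparison alone, so whether the calls hold under such pairing was not tested. In SOMB against SOMA the fit of all 29 libraries gave 343 higher genes in place of 575, and lists fell from 14 to 6 with an estimated correlation and 13 with fry. Leaving out 1 library gave 357 (SOMA4) to 591 higher and 443 (SOMA3) to 639 lower, and 14 to 20 lists. In SOMD against SOMA lists fell from 17 to 3 with an estimated correlation and rose to 21 with fry; leaving out 1 library gave 1044 to 1661 higher and 883 to 1341 lower, and 15 to 24 lists.

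In SOMC against SOMB the counts of 68 and 51 became 158 and 127 with DESeq2, 20 and 19 in the fit of all 29 libraries, 122 and 106 with the share of reads in no feature as a term, and 11 and 4 with nearly identical libraries summed, which leaves fewer libraries. Lists fell from 20 to 2 with an estimated correlation and 2 with fry. Leaving out 1 library gave 17 to 86 higher and 9 to 69 lower, and 15 to 22 lists: 28 and 20 without SOMB1, 17 and 9 without SOMB4, 21 and 12 without SOMC1, 17 and 11 without SOMC4, 41 and 31 without SOMD4, 45 higher without SOMC2 and 23 lower without SOMC3.

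In SOMD against SOMC the counts of 176 and 149 became 76 and 66 in the fit of all 29 libraries, 348 and 276 with the share of reads in no feature as a term, and 20 and 32 with nearly identical libraries summed; DESeq2 called 240 lower. Lists fell from 14 to 0 with an estimated correlation (camera; lowest adjusted p 0.0531) and 7 with fry. Leaving out 1 library gave 61 to 213 higher and 69 to 189 lower, and 12 to 18 lists: 82 and 77 without SOMC1, 78 and 84 without SOMC4, 64 and 70 without SOMD1, 61 and 69 without SOMD4, and 90 higher without SOMC3.

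In MUT against WT the counts of 133 and 22 became 213 and 43 with library totals and 260 and 65 without a filter. They became 382 and 137 with replicate number as a block, 482 and 228 with DESeq2, and 16 and 4 in the fit of all 29 libraries. After the trend over length and GC content was removed they were 41 and 9, of which 39 and 4 were also called in the main fit. The trend setting tests 12600 genes. The low-Xist setting leaves 1 MUT library, and with Xist as a term the difference rests on that same library, MUT1. No counts are given for these 2 settings, which cannot separate sex from mutation. Lists fell from 8 to 0 with an estimated correlation (camera; lowest adjusted p 0.177) and 2 with fry. Leaving out 1 library gave 1 to 115 higher and 0 to 40 lower, and 7 to 12 lists: 17 and 5 without MUT1, 2 and 0 without MUT2, 1 and 0 without MUT3, 19 and 0 without WT1, 14 and 0 without WT2, and 40 lower without WT3.

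For the sets changed by LDN and SAG, the camera adjusted p with an estimated correlation was 0.188 for the lowered set in SOMC against SOMB and 0.226 in SOMD against SOMC. A direction changed for 3 lists with 1 library out, and the cause was not tested. These are ribosomal proteins in DIR against CTRL without DIR3 (camera adjusted p = 0.665, and down to 1.26e-08 without DIR2) and, in SOMC against SOMB without SOMB2, ribosomal proteins (0.661, down to 2.63e-10 without SOMC3) and the respiratory chain (0.855, down to 1.12e-08 without SOMB3). Depth limits genes of low count: SOMD2 holds 11541131 counts, and PEAT has 3 counts in all SOMA libraries together.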

Other observations

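All tests in this part compare the libraries in every other split into groups of the same sizes, and were chosen only after the result was seen. The share of genes whose groups did not overlap was 8.96% in DIR against CTRL and 6.05 and 7.65% in SOMC against SOMB and SOMD against SOMC (chance gives 2.86%), 16.0 and 28.3% in SOMB and SOMD against SOMA (chance 5.71%), and 22.1% in MUT against WT (chance 10%).

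For the number of genes changed, 1 of 35 splits, the real one, gave as many in DIR against CTRL (106, highest other 0), in SOMB against SOMA (1206, highest other 219), in SOMC against SOMB (119, highest other 2), in SOMD against SOMC (325, highest other 2) and in SOMD against SOMA (2715, highest other 1513). The splits with 1513 and 219 genes put SOMD3 or SOMB3 with the 3 SOMA libraries against the rest, and keep most of the real contrast. Splits of the same form gave 828 genes with SOMD2, 205 with SOMB1, 54 with SOMB2 and 0 with SOMD1, SOMD4 or SOMB4. The cause of this range was not tested. The splits count the nearly identical SOMC1 and SOMC4, and SOMD1 and SOMD4, as separate libraries and were not repeated with them summed. Same-number libraries deviate together in SOMB against SOMA and in SOMD against SOMC. The splits that part all of their pairs are 8 in each, too few for a share under the threshold. The real one gave the most genes among them (1206, highest other 54, and 325, highest other 0), while splits that part fewer pairs gave up to 219 and 2. In SOMC against SOMB and SOMD against SOMA some libraries with other numbers deviate together (SOMB3 and SOMC2 by 0.300, SOMA4 and SOMD3 by 0.241), which the splits do not take into account. In DIR against CTRL libraries deviate together along the share of reads aligned at more than 1 place (CTRL1 with DIR1 by 0.701 and with DIR2 by 0.675). Of the 30 splits that part these 3 libraries 1 to 2, as the real one does, the real one alone gave as many genes (106, highest other 0). Only in DIR against CTRL do the splits thus argue against chance, as far as this share accounts for what its libraries have in common. The share was chosen after seeing the data, and the labels do not say whether the replicates are separate cultures. Chance is therefore not excluded even there. The 10 splits of MUT and WT are too few for a share under the threshold; the real split gave 155 genes as the only 1 of 10, and the highest other 7.

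For the number of lists past the threshold, chance was not excluded in DIR against CTRL (18; 4 of 35 splits gave as many, highest other 19), SOMB against SOMA (14; 18 splits, highest other 21), SOMD against SOMC (14; 14 splits, highest other 22) or SOMD against SOMA (17; 11 splits, highest other 24). Of the 8 splits that part all pairs 5 gave as many in SOMB against SOMA (highest other 20) and 1 in SOMD against SOMC (highest other 13). In SOMC against SOMB 1 of 35 splits gave as many (20, highest other 19), with nearly identical libraries counted as separate and those that deviate together not taken into account, so chance is not excluded there either. In MUT against WT the splits are too few; 9 of 10 gave at least the 8 lists of the real one, the highest other 18.

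For the sets changed by LDN and SAG, 1 of 35 splits of SOMB and SOMC gave as low an adjusted p (camera adjusted p = 1.92e-07, lowest other 2.17e-07), with the same limits. Chance was not excluded in SOMB against SOMA (31 splits, lowest other 4.94e-07), SOMD against SOMC (7 splits, lowest other 1.26e-09) or SOMD against SOMA (28 splits, lowest other 4.06e-08). Of the 8 splits that part all pairs 8 gave as low a value in SOMB against SOMA and 2 in SOMD against SOMC (lowest other 9.19e-06 and 8.72e-07).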
